A study of Rattus norvegicus with 14 samples.

How the data were processed

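The transcriptomes of pineal glands and retinas of Sprague-Dawley rats were sampled over 1 day. Rats were kept in 14 h of light and 10 h of darkness, with lights on at zeitgeber time 0 (ZT0). Each tissue was collected at ZT1, ZT7 and ZT13 in the light and at ZT15, ZT19 and ZT23 in the dark, and each of these 12 libraries came from a pool of 10 animals. Further pools of mixed tissue (15 tissues, the retina among them, from 3 animals) were collected at ZT7 and at ZT19, which gave 14 libraries in all.

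Per the labels' protocols, 10 µg of total RNA was enriched for polyadenylated RNA, fragmented and copied with random primers, the libraries were amplified with 16 cycles of PCR, and 6 barcoded libraries shared a lane, read as 101-base paired ends. Whether the reads keep strand was not given in the sources used here, so overlapping genes on opposite strands could not be told apart. The submitters' processing notes name TopHat 1.3.1, Cufflinks 1.2.0 and the rn4 genome build, without saying more of their roles. The deposited values were FPKM (fragments per kilobase of transcript, relative to all fragments of the library) per RefSeq transcript, 1 value per transcript and library, and no read counts were used. The FPKM scale sets each library relative to its own fragments, so a group of very abundant transcripts lowers all others.

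The table held 16932 transcripts. FPKM values of transcripts with the same gene ID were summed, which gave 16472 genes, of which 342 had several transcripts. 11 transcripts without a gene ID were kept under their own identifiers, and 24 transcripts whose symbols had turned into dates were renamed from a table of current RefSeq genes of the GRCr8 assembly, which was used for names alone and held 16299 of the gene IDs. Coordinates are those of the deposited table in rn4. Start positions in the table count from 0: with that reading 99.7% of 1192 single-exon olfactory receptor spans were whole codons, against 0.1% otherwise, so 1 was added to each printed start.

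Exact depth was not available from FPKM. The FPKM worth of 1 fragment in a transcript of 1 kb was estimated from olfactory receptor transcripts above 0, at the 10th percentile of their values. These were 12 to 40 transcripts per library (18 in pineal ZT19), so the estimate is rough. It ranged from 0.0216 in the retina ZT23 library to 0.0527 in the pineal ZT19 library, an estimated relative depth of 0.41 of the deepest for pineal ZT19. Values near this floor carry large counting error. Some genes that every cell uses were listed near 0: Gapdh lay between 0.0715 and 0.567 FPKM and Hspa8 between 0 and 0.162 FPKM over the 14 libraries. A value of 0 is therefore given only as listed, and members of multigene families (the crystallins, the globins, Zrsr1) are uncertain.

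Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), on genes of at least 1 FPKM in at least 2 libraries of the fit: 10416 genes in the time series and 11656 in the tissue comparisons. The pseudocount of 1 FPKM lowers the fold of weakly expressed genes. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and tests were two-sided unless said otherwise. Each tissue and time had 1 library, so the error is what a model left over (6 residual degrees of freedom in the time series and 11 in the tissue fit), and it holds both the spread between pools and any departure from the model. A 24-h cosine and sine per tissue tested rhythm (moderated F test). The phase model compared late dark (ZT19 and ZT23) with light (ZT1, ZT7 and ZT13) and gave ZT15 its own mean. Interaction contrasts tested whether rhythms or late dark effects differed between the tissues. In the tissue comparisons the libraries of a tissue served as its replicates (6 pineal, 6 retina and 2 mixed), and genes above both others were those for which the larger of both p-values passed after adjustment. The mean ± SD of FPKM is given over the libraries of a group.

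Gene lists were tested with camera (inter-gene correlation preset at 0.01, and again with an estimated correlation) where at least 5 members were tested, and rhythmic members were counted against other genes with Fisher's exact test, adjusted over the lists within each tissue. The pathway lists covered melatonin synthesis, adrenergic and cAMP signalling, immediate early genes, the clock, phototransduction, photoreceptor structure and the visual cycle, pineal and photoreceptor transcription factors, thyroid hormone handling, dopamine and melatonin receptors, heat shock and chaperones, cholesterol synthesis, glycolysis, and ID and BMP targets. Marker lists covered retinal cell types, pigment epithelium, lens, blood, microglia, endothelium, meninges, choroid plexus, brain neurons, oligodendrocytes and the organs of the mixed pools. The lists, the tests, the named genes and the alternatives were fixed before the data were examined, except where said. Named genes were taken from a fixed set (Aanat, Tph1, Asmt, Dio2, Crem, Fosl2, Per1, Nr1d1, Dbp, Arntl, Sag and Crx among them), the 10 largest changes per comparison and direction among genes past the threshold with a mean of at least 10 FPKM, and up to 4 members per list and direction. Fosl2 was not listed in the table used here.

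On simulated data with 178 to 200 changed genes per comparison, a log2 change of 1 was recovered for 36.3% of genes in the pineal rhythm test, 46.7% in the retina rhythm test, 83.2% and 77.9% in the late dark tests of pineal gland and retina, 90.9% for pineal gland against retina, 81% for pineal gland against mixed tissue and 79% for retina against mixed tissue. A log2 change of 2 was recovered for 89.7%, 91.9%, 94.8%, 97.8%, 92.9%, 96% and 98%. Differences of rhythm were recovered for 8.9% of genes at a size of 1 and 71.1% at 2, and differences of the late dark effect for 58.2% and 86.3%. The size of a rhythm was its peak to trough, with peak times drawn at random, and that of other changes a shift of the group mean. False calls made up between 1% and 7.6% of the calls. Noise was drawn for each gene and library on its own, and the changes had the form of the model fitted. These shares therefore do not give the false calls in the real libraries, where genes can move together and depart from the model. Camera called 10 of 10 changed lists and 0 of 40 unchanged lists with either correlation. These lists were simulated without correlation between genes. The run therefore cannot show which setting limits false calls where genes move together, and estimated correlations in the data reached 0.909 (lens markers, late dark tests).

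The alternatives were a pseudocount of 0.1, other expression filters, quantile normalization, median ratio scaling, limma without the trend, each tissue fitted alone, other groupings of ZT1 and ZT15, time of day as a block in the tissue comparisons, ZT7 and ZT19 alone in the tissue comparisons, and leaving out each library in turn. Labels gave no replicate numbers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.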

Results

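Expression of 16472 genes was measured as FPKM in pineal glands and retinas of rats at 6 times of day, and in mixed tissue pools at mid-day and mid-night. The pineal gland makes melatonin at night, and the retina shares many photoreceptor genes with it. The series was made to find transcripts that change over the day and transcripts enriched in the pineal gland. Summed FPKM per library lay between 152281 (retina, ZT23) and 212634 (mixed tissue, ZT7), and 8852 to 11399 genes reached 1 FPKM. Tph1, the first enzyme from tryptophan towards serotonin, was the most abundant transcript in each pineal library, with 1.82% to 2.15% of all FPKM. Correlations of log2 values across genes, which are not independent replicates, lay between 0.975 and 0.994 within the pineal gland and between 0.989 and 0.996 within the retina. Between the tissues they were 0.846 to 0.868. Each tissue and time had 1 library, without replicates, so single-time values have no error of their own.

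The first question was which transcripts follow a 24-h rhythm in the pineal gland. The largest fitted rhythms belonged to genes with little expression at ZT7 and ZT13 and more late at night. At ZT1, also in the light, the genes named in this paragraph ranged from 1.9 FPKM (Sik1) to 395.6 (Aanat). Slc15a1, a peptide transporter (gene ID 117261, rn4 chromosome 15, 106550096 to 106592594), stood at 0.708 FPKM at ZT7 and 270.03 FPKM at ZT19. Its fitted peak to trough was 9.07 on the log2 scale (adjusted p = 0.000294). Aanat, the penultimate enzyme of melatonin synthesis (gene ID 25120, rn4 chromosome 10, 106709371 to 106713683), lay at 7.05, 6.35 and 5.13 FPKM at ZT7, ZT13 and ZT15. At ZT19, ZT23 and ZT1 it lay at 650.3, 857 and 396 FPKM (peak to trough 8.79, peak at ZT22.4, adjusted p = 0.000179). Fitted peaks between ZT22.6 and ZT23.2 were found for the copper transporter gene Atp7b (7.74, adjusted p = 0.000419), Hhip (5.57, adjusted p = 1.01e-05) and Fcer1a (5.57, adjusted p = 0.00312). The dopamine receptor gene Drd4 (5.39, adjusted p = 0.000117) and Ribc2 (4.75, adjusted p = 0.000535) peaked in the same hours. Crem (5.18), Dclk3 (4.96) and Sik1 (4.88) peaked earlier, between ZT20.7 and ZT21.1, with adjusted p of 0.00179, 0.0116 and 0.0445. These ranges are those of the fitted cosine and can exceed the data: the observed log2 values spanned 7.58 for Slc15a1, 7.13 for Aanat and 6.59 for Atp7b, and the fitted range was above the observed one in 891 of the 2160 rhythmic pineal genes and 85 of the 106 of the retina.

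Asmt, the last enzyme of melatonin synthesis, had a smaller rhythm (peak to trough 0.76, peak at ZT23.8, adjusted p = 0.0259). Tph1 (0.33, adjusted p = 0.193), Dio2 (3.13, adjusted p = 0.17) and the photoreceptor factor gene Crx (0.70, adjusted p = 0.0734) did not pass. Without the pineal ZT7 library Dio2 (fitted peak to trough 7.46, adjusted p = 0.0211) and Crx (1.29, 0.0202) passed, Crx also without ZT1 (0.0244). The ranges of Tph1, Sik1 and Dclk3 were then 0.61, 9.25 and 8.03, and without ZT19 those of Dio2 and Tph1 were 0.62 and 0.20. Asmt missed without ZT13 (0.105) or ZT23 (0.134) and Dclk3 without ZT23 (0.0556). Sik1 missed without pineal ZT13, ZT19 or ZT23 or any 1 retina library (0.0661 to 0.141). Over all alternatives the adjusted p ran from 0.0211 to 0.322 for Dio2, 0.0202 to 0.25 for Crx and 0.0151 to 0.134 for Asmt. For Dclk3 it ran from 0.00146 to 0.0775 and for Sik1 from 0.00101 to 0.15.

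In all, 2160 of 10416 tested genes (20.7%) passed the rhythm test in the pineal gland, 1472 with a fitted peak in the light and 688 in the dark. The fitted peak to trough was at least 4-fold for 128 of them. Fitted peaks gathered late in the light phase (451 genes between ZT8 and ZT10, 423 between ZT10 and ZT12) and late in the dark phase (224 between ZT20 and ZT22, 241 between ZT22 and ZT24). No library was taken between ZT7 and ZT13, so peak times there come from the fitted curve. By the highest library the split was more even, with ZT1 for 146, ZT7 for 523 and ZT13 for 421 genes in the light. In the dark it was ZT15 for 424, ZT19 for 257 and ZT23 for 389, while 94 fitted peaks lay between ZT14 and ZT16. Among genes with a fitted peak to trough of at least 2-fold the fitted peaks were also split more evenly, with 372 in the light and 317 in the dark. Quantile normalization gave 1150 peaks in the light and 797 in the dark, and median ratio scaling 1168 and 958, with 1708 and 1801 of the 2160 genes called again. The count was 1280 without ZT13 (824 in the light, 456 in the dark) and 889 without ZT23 (572 and 317). With the pineal gland fitted alone it was 535 (311 and 224).

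**Figure D1:**
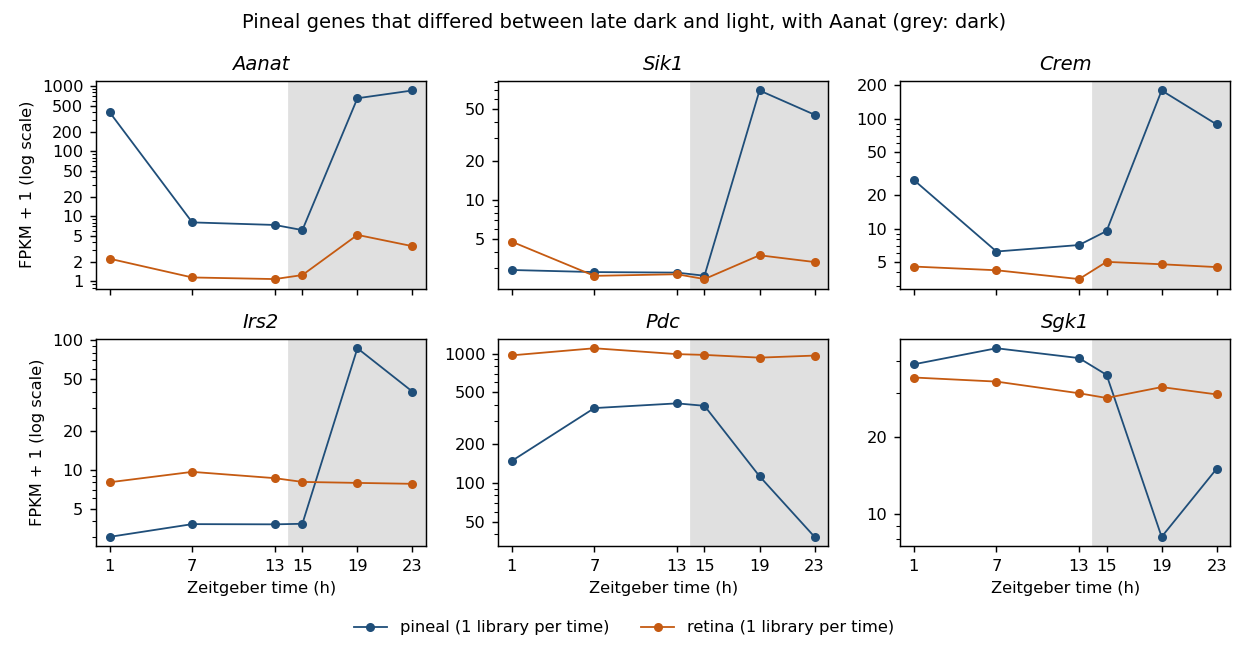
Expression of 6 genes over the day in the pineal gland (blue) and retina (orange), as FPKM + 1 on a log axis against zeitgeber time in hours, with 1 library per point and darkness in grey. In the pineal gland Aanat stood at 5.13 FPKM at ZT15 and 650.3 at ZT19, and Sgk1 at 34.3 and 7.13.

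Clock genes were the list with the clearest pineal rhythm. Of 17 tested members 13 passed (14 when adjusted over the list alone), 8 peaking in the dark and 5 in the light, more than among other genes (Fisher's exact test, adjusted p = 3.89e-05). Here and for the lists below, Fisher's exact test takes genes as independent and makes no allowance for genes that move together. The activator Arntl peaked at ZT3.96 (peak to trough 2.22, adjusted p = 0.000102) and Nr1d1, a repressor of Arntl, at ZT12.8 (2.49, adjusted p = 1.76e-05). The output gene Dbp peaked at ZT14.4 (2.53, adjusted p = 1.29e-05). The repressors Per1 and Per2 peaked at ZT18.9 (1.98, adjusted p = 0.0337) and ZT19.2 (2.21, adjusted p = 0.000107). Per1 missed the threshold without pineal ZT13, ZT19 or ZT23 or any 1 of the 6 retina libraries (adjusted p 0.0518 to 0.135, and 0.0043 to 0.135 over all alternatives). Its peak to trough was 1.07 without pineal ZT19 and 3.80 without ZT7.

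Heat shock and chaperone genes were rhythmic for 11 of 18 members (15 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00331), 9 of them with peaks in the dark. Hspa5, an endoplasmic reticulum chaperone, lay at 70.1 FPKM at ZT7 and 305 at ZT23 (peak at ZT21.8). Hspa1a peaked at ZT19.4, Hsph1 at ZT21.3 and the stress response factor gene Xbp1 at ZT21.1. Of the adrenergic and cAMP signalling genes 10 of 19 were rhythmic (10 adjusted over the list alone; adjusted p = 0.0209), 9 of them peaking in the dark.

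Phototransduction genes were rhythmic in the pineal gland for 11 of 28 members (13 adjusted over the list alone), and 9 of these peaked in the light phase. Their share did not differ from that of other genes after adjustment (Fisher's exact test, adjusted p = 0.189). Sag, the rod arrestin gene, lay at 46.9 FPKM at ZT1 and 350.4 at ZT15 (peak to trough 2.80, peak at ZT13, adjusted p = 1.29e-05). Pdc, which binds transducin subunits, lay at 411 FPKM at ZT13 and 37.2 at ZT23 (3.21, peak at ZT10.4, adjusted p = 0.00292). Opn1sw, the short-wavelength cone opsin gene, lay at 44.8 FPKM at ZT7 and 10.2 at ZT19 (2.08, adjusted p = 0.00138). Melatonin synthesis had 6 of 11 members rhythmic (6 adjusted over the list alone, adjusted p = 0.104). For the other pathway lists, with counts adjusted over the list alone in brackets, 3 of 9 genes of thyroid hormone handling (3), 6 of 15 transcription factors (7) and 3 of 6 dopamine and melatonin receptors (3) were rhythmic. So were 4 of 12 immediate early genes (4), 5 of 17 genes of photoreceptor structure (8), 4 of 18 of cholesterol synthesis (6), 3 of 19 of glycolysis (2) and 1 of 8 ID and BMP targets (3). Their adjusted p lay between 0.463 and 1.

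**Figure D2:**
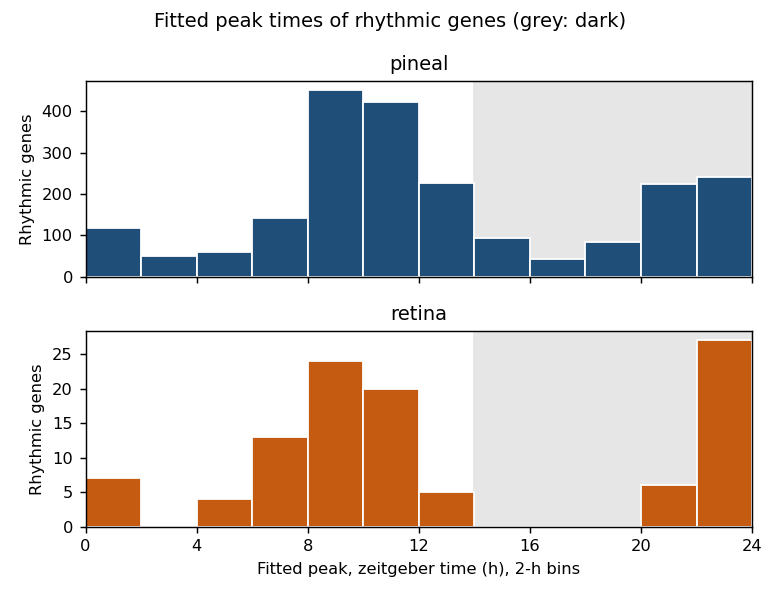
Number of rhythmic genes per 2-h bin of fitted peak time in the pineal gland (2160 genes) and retina (106 genes), against zeitgeber time in hours, with darkness in grey. Fitted pineal peaks gathered between ZT8 and ZT12, where no library was taken, and between ZT20 and ZT24.

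In the retina Pax4, a transcription factor gene, had the largest fitted rhythm (9.81 FPKM at ZT23 and 53.3 at ZT7, peak to trough 2.40, peak at ZT10.8, adjusted p = 0.0187). Late at night peaked the phosphodiesterase gene Pde8a (2.24, ZT21.9, adjusted p = 0.0091), Ctnnal1 (2.20, ZT22.6, adjusted p = 0.00765) and the potassium channel gene Kcnv2 (1.87, ZT22.7, adjusted p = 0.0251). The lens gene Mip (2.15, ZT22.2, adjusted p = 0.047) and Ypel4 (1.87, ZT23.3, adjusted p = 0.00765) peaked at similar times. Asns, an asparagine synthetase gene, peaked in the day (1.87, ZT8.5, adjusted p = 0.0091), as did Mast2 (1.76, ZT11.1, adjusted p = 0.00187) and Acbd7 (2.05, ZT9.91, adjusted p = 0.0343). Junb peaked at ZT20.4 (1.87, adjusted p = 0.0215). Lens genes, markers of another eye tissue, were highest in the ZT19 library and next highest in ZT1 (Crygc 541 and 208 FPKM, against 21.3 at ZT7). Each of the rhythmic genes named here but Mast2 missed the threshold without certain single libraries, with adjusted p between 0.0501 and 0.152. These were retina ZT1, ZT15 or ZT23 for Pax4, ZT1 or ZT13 for Pde8a and Ypel4, ZT13 or ZT23 for Ctnnal1, ZT23 for Asns (whose range was 1.09 without ZT7), and any 1 of the 6 for Junb and Kcnv2. For Acbd7 they were each retina library but ZT13, and pineal ZT23. For Mip they were each retina library but ZT23, and pineal ZT1, ZT13 or ZT23.

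In all, 106 of 10416 genes (1.02%) passed the rhythm test in the retina, 73 with peaks in the light and 33 in the dark, and 2251 genes had an unadjusted p under 0.05. Of the clock genes 1 of 17 passed (1 adjusted over the list alone), the kinase gene Csnk1e, with 15.9 FPKM at ZT13 and 51.6 at ZT19 (adjusted p = 0.0453). Arntl lay between 24.5 and 32.1 FPKM over the 6 retina libraries and Per2 between 3.9 and 4.74. Of the phototransduction genes 0 of 28 passed in limma's test (5 adjusted over the list alone). The count of rhythmic genes was 12, 28, 27, 36, 31 and 13 without the retina libraries at ZT1, ZT7, ZT13, ZT15, ZT19 and ZT23. Without the pineal libraries at ZT13, ZT15, ZT19 and ZT23, which share the error estimate, it was 60, 193, 415 and 63. Fitted alone, with its own error, the retina gave 781 genes, more than the pineal gland fitted alone. Which tissue had more rhythmic genes thus depended on the shared error estimate. Without the retina ZT1 and ZT19 libraries together the count was 4. Quantile normalization gave 74 light and 99 dark peaks and median ratio scaling 39 and 85, with 91 and 77 of the 106 genes called again.

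**Figure D3:**
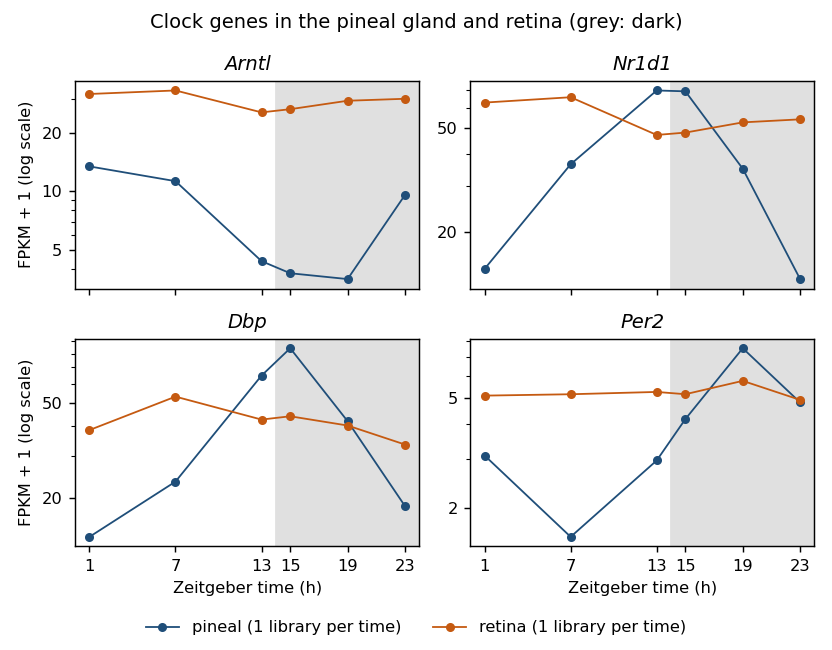
Clock genes over the day in the pineal gland (blue) and retina (orange), as FPKM + 1 on a log axis against zeitgeber time in hours, with 1 library per point and darkness in grey. Nr1d1 lay between 12.2 and 68.8 FPKM in the pineal gland, and Arntl between 24.5 and 32.1 FPKM in the retina.

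Rhythms were also compared between the tissues. In a test of the difference itself 516 of 10416 genes passed. Nr1d1 (adjusted p = 0.000239), Sag (0.000325), Dbp (0.000554), Arntl (0.00502), Aanat (0.0141) and Crem (0.0348) were among them, and Per1 was not (0.153). Rhythm was called in both tissues for 35 genes, where independent lists would share 21.98. Both lists came from 1 fit whose error estimate the tissues share. The fitted peaks of 29 of the 35 genes lay within 6 h, as for Adra1b, an alpha-adrenergic receptor gene (ZT22.6 and ZT21.8), Junb (ZT19.2 and ZT20.4) and Pax4 (ZT12.6 and ZT10.8). Fitted peaks gathered between ZT8 and ZT12 and between ZT20 and ZT24 in both tissues. Near peaks can therefore arise without a shared rhythm, and the count of 29 was not tested. The count of differences was 314 and 237 without pineal ZT13 and ZT23, and 828 and 797 without pineal ZT7 and ZT19. Without retina ZT1, ZT7, ZT13, ZT15, ZT19 and ZT23 it was 221, 193, 188, 251, 286 and 178, and without retina ZT1 and ZT19 together 25.

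The second question was which genes differ between late dark and light. In the pineal gland Sik1, a kinase gene of cAMP signalling (gene ID 59329, rn4 chromosome 20, 10282203 to 10291735), rose from 1.82 ± 0.0693 FPKM in light (SD, n = 3) to 56.2 ± 17.1 in late dark (SD, n = 2). The log2 change was 4.31 with an SE of 0.25 (adjusted p = 1.69e-05). Irs2, an adaptor of insulin signalling, rose from 2.53 ± 0.44 to 62.4 ± 33 FPKM (log2 change 4.07, SE 0.26, adjusted p = 2.32e-05). Ptch1, the hedgehog receptor gene, rose from 12.1 ± 3.56 to 169.7 ± 32 FPKM (3.73, SE 0.19, adjusted p = 9.36e-06), and Dusp1, a MAP kinase phosphatase gene, to 52.2 FPKM (3.64, adjusted p = 4.36e-05). Further large rises were those of Slc15a1 (5.22, adjusted p = 0.032), Atp7b (4.21, adjusted p = 0.0499) and Dclk3 (3.79, adjusted p = 0.000341). Zrsr1 (3.61, adjusted p = 3.63e-05), Crem (3.57, adjusted p = 0.00342) and Fcer1a (3.03, adjusted p = 0.0348) followed. In each of these 10 genes both late dark libraries lay above the 3 light libraries. The calls for Slc15a1, Atp7b and Fcer1a were lost without pineal ZT7, ZT13, ZT19 or ZT23 (adjusted p 0.0698 to 0.195) and without retina ZT7, ZT13, ZT19 or ZT23 (0.0545 to 0.0795). Those for Atp7b and Fcer1a were also lost without retina ZT1 (0.0649 and 0.0522). Over all alternatives the adjusted p of the 3 genes ran from 4.89e-08 to 0.534, 2.26e-06 to 0.628 and 1.17e-06 to 0.712.

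Aanat had a log2 difference of 4.71 between late dark and light (SE 1.32, adjusted p = 0.0542), with 396 FPKM in the ZT1 library of the light group. Without that library the difference was 6.60 (adjusted p = 1.15e-06), and over the alternatives the adjusted p lay between 3.27e-07 and 0.601. Dio2, the thyroid hormone activating deiodinase gene, stood at 25.4 FPKM at ZT19 and at 1.3 FPKM or less in the other pineal libraries (2.45, adjusted p = 0.0592). Without ZT23 the difference was 4.21 (adjusted p = 6.06e-06, the lowest of a range up to 0.476), and without ZT19 it was 0.69.

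The largest fall was that of Ccl9, a chemokine gene, from 18.1 ± 6.18 FPKM (SD, n = 3) to 1.53 ± 1.24 (SD, n = 2), a log2 change of -2.96 with an SE of 0.33 (adjusted p = 0.000797). Sgk1, a kinase gene, fell from 40.6 ± 3.07 to 10.6 ± 4.91 FPKM (-1.91, adjusted p = 0.000797). Hs3st2 (-2.65, adjusted p = 0.0231), Ptpn21 (-2.38, adjusted p = 0.000259), the adenylyl cyclase gene Adcy1 (-2.24, adjusted p = 0.0113) and St8sia3 (-2.18, adjusted p = 0.00886) fell as well. So did Pdc (-2.12, adjusted p = 0.0234), Ndrg1 (-1.74, adjusted p = 0.00562), Cfl2 (-1.62, adjusted p = 0.000797) and Hook1 (-1.57, adjusted p = 0.022). The calls for Hs3st2, Pdc and Hook1 were lost without pineal ZT7, ZT13 or ZT23 (adjusted p 0.0619 to 0.117), with Pdc at -1.34 without ZT23. The call for Adcy1 was lost without ZT7 (0.0501) or ZT23 (0.0557). Those for St8sia3 and Ndrg1 were lost without ZT23 (0.0513) and ZT19 (0.0649). Over all alternatives the adjusted p of these 6 genes ran from 9.31e-05 to 0.501.

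Across the pineal transcriptome 317 genes rose and 441 fell in late dark, and 137 and 74 of these changed at least 2-fold. The median of all tested genes lay at -0.12 on the log2 scale in the pineal gland and -0.11 in the retina. Changes were tested against 0, so they and the counts include that shift. Scaling turned the split, with 383 higher and 252 lower after quantile normalization and 484 and 273 after median ratio scaling. Without ZT1 the counts were 538 and 1062, without ZT7 133 and 126, without ZT13 194 and 207, and without ZT19 90 and 73. Without retina ZT19 or ZT23 272 and 271 were lower. With the pineal gland fitted alone the counts were 69 and 52. Grouping ZT15, where Sik1 stood at 1.62 FPKM and Ptch1 at 11.9, with the dark libraries left 0 and 0 in limma's test (403 and 802 at an unadjusted p under 0.05). The pineal ZT19 library also had the lowest summed FPKM (163087, against 174889.3 to 180522.1 in the others).

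By list, 8 of 19 adrenergic and cAMP signalling genes rose and 1 fell (10 and 3 adjusted over the list alone). Sik1, Crem, Pde4b (log2 change 2.47), Nr4a1 (2.83) and Gem (1.75) were among the higher, and Adcy1 was the lower (camera, adjusted p = 2.87e-08, and adjusted p = 0.0553 with an estimated correlation). Among 12 immediate early genes Dusp1, Btg2 (1.47) and Junb (0.96) were higher and Jun lower (-0.90). The counts were 5 and 1 adjusted over the list alone (camera adjusted p = 8.36e-05, and adjusted p = 0.274 with an estimated correlation). Of 18 heat shock genes 3 rose, Hspa1a (from 18.8 ± 8.06 to 41.7 ± 3.37 FPKM), Xbp1 (1.11) and Dnajb1 (0.99), and 0 fell (6 and 1 adjusted over the list alone). Camera gave an adjusted p = 0.000231, and an adjusted p = 0.321 with an estimated correlation. Of 17 clock genes Cry2 (1.51), Per1 (1.50) and Per2 (from 1.54 ± 0.842 to 5.17 ± 1.93 FPKM) rose and Rora fell (-0.86), with 3 and 1 adjusted over the list alone. The adjusted p was 0.00403, and adjusted p = 0.274 with an estimated correlation. The Per1 call was lost without pineal ZT7 (adjusted p = 0.0566) or ZT19 (0.93 on the log2 scale, adjusted p = 0.0991), in a range from 0.00128 to 0.324.

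Among phototransduction genes 0 of 28 rose and 6 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.389). The 6 were Pdc, Opn1sw (-1.35), Cnga1 (adjusted p = 0.00775), Rgs9bp (-1.04), Guca1b (-0.77) and Slc24a2 (-0.62). Melatonin synthesis had 1 of 11 members higher (3 adjusted over the list alone). This was Mat2a, which makes the methyl donor of the last step, with 11 FPKM at ZT13 and 81.5 at ZT19 (log2 change 2.11, adjusted p = 0.000797). The median of the list was -0.04, its mean 0.58 and camera's direction up (adjusted p = 0.0901). Of 15 transcription factors Bsx (2.10) and Lhx4 (0.66) rose and Isl2 fell (-1.21), while Crx did not pass (0.56, adjusted p = 0.0626). Without ZT1 the adjusted p of Crx was 0.041, in a range from 0.0203 to 0.488. The median of this list was -0.04 and its mean 0.01 (3 higher and 4 lower adjusted over the list alone; camera up, adjusted p = 0.225). Of 6 receptors Drd1a rose (0.98), at 1.84 FPKM or less (2 higher adjusted over the list alone).

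Markers of other cells were followed in late dark as well. Blood markers had a median of -0.61 over 7 members, of which 0 passed in limma's test (4 lower adjusted over the list alone). The camera adjusted p was 0.0415, and adjusted p = 0.63 with an estimated correlation. Microglia (1 of 11 lower, 3 adjusted over the list alone, median -0.39), oligodendrocyte (2 of 6 lower, -0.38) and meningeal markers (1 of 11 lower, -0.34) had camera adjusted p of 0.056, 0.056 and 0.234. None of the 5 calls of camera in the pineal gland held with an estimated correlation.

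In the retina, 1 gene was higher in late dark and 0 were lower in limma's test, with 166 and 1072 at an unadjusted p under 0.05. This unadjusted split depended on scaling. It was 472 higher and 529 lower after quantile normalization, and 508 and 382 after median ratio scaling. The gene past the test was Ptpn20, a phosphatase gene chosen after its values were seen. It stood at 0.188 to 0.605 FPKM in light and at 3.71 and 2.98 FPKM in late dark (log2 change 1.69, SE 0.15, adjusted p = 0.00297). Egr1, an immediate early gene, stood at 4.19 FPKM at ZT7, 600.1 at ZT15, 299 at ZT19 and 169.9 at ZT23 (late dark log2 difference 3.96, SE 0.68, adjusted p = 0.116). Fos stood at 3.78, 51, 47 and 25.1 FPKM at these times (2.15, adjusted p = 0.237). The light libraries at ZT1 and ZT13 also enter these differences, and for Egr1 and Fos they lay above ZT7 on average. Of the immediate early genes 0 of 12 passed (5 higher and 1 lower adjusted over the list alone), and of the lens markers 0 of 8 (0 adjusted over the list alone, median 1.17). Camera called these lists at adjusted p of 5.61e-06 and 2.84e-09, and glycolysis and bipolar cell markers at 0.0215 each. The adjusted p was 0.381, 0.381, 0.503 and 0.381 with an estimated correlation. Blood markers had a median of -0.59 over 7 members, with 0 past the test and 4 lower adjusted over the list alone (camera adjusted p = 0.0735). Pigment epithelium markers had a median of -0.27 over 7, with 0 past the test and 1 higher and 3 lower adjusted over the list alone (0.667). Without retina ZT19 0 genes were higher (65 unadjusted), and without retina ZT1 39 were higher and 35 lower.

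The late dark effect itself differed between the tissues for 74 genes. Irs2 (pineal minus retina 4.22), Sik1 (4.17), Dclk3 (3.73), Ptch1 (3.62), Zrsr1 (3.55) and Dusp1 (2.60) had the larger rise in the pineal gland. Ptpn21 (-2.16), Sgk1 (-1.82) and Cfl2 (-1.71) had the larger fall. For Crem (3.38, adjusted p = 0.0756), Slc15a1 (5.22, adjusted p = 0.256) and Aanat (adjusted p = 0.612) the difference did not pass. The count was 384, 36, 28 and 186 without pineal ZT1, ZT7, ZT19 and ZT23, and 22, 30, 7 and 10 without retina ZT7, ZT13, ZT19 and ZT23.

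The third question was which genes set the pineal gland apart. Against the retina, the pineal gland held the enzymes of melatonin synthesis. Tph1 (gene ID 24848, rn4 chromosome 1, 97186071 to 97207551) stood at 3539 ± 360 FPKM against 0.448 ± 0.0532 (SD, n = 6 each; log2 difference 11.25, SE 0.07, adjusted p = 9.22e-21). Ddc stood at 175.5 ± 33.8 against 0.121 ± 0.0617 (7.28, adjusted p = 2.23e-16). Gch1, which starts the synthesis of the hydroxylase cofactor, stood at 103.8 ± 29.2 against 0.313 ± 0.219 (6.29), and Asmt at 318 ± 77.1 against 6.64 ± 1.62 (5.38, adjusted p = 3.25e-13). Of the 11 members 9 were higher and 0 lower (9 and 0 adjusted over the list alone). The list call held with an estimated correlation (camera, adjusted p = 0.000183, and adjusted p = 0.0478 with an estimated correlation). With Tph1, Ddc and Gch1 but not Asmt, the 10 largest differences included the lipoxygenase gene Alox15 (527 ± 156 against 0.969 ± 0.247 FPKM). Esm1 (117.6 ± 8.94 against 0.12 ± 0.0501) and the zinc transporter gene Slc39a4 (log2 difference 6.12) were among them too. Car3 (adjusted p = 3.23e-13), Bsx, listed at 0 in each retina library, the nicotinic receptor gene Chrnb4 (5.50) and the collagen gene Col8a1 (5.48) completed them. In each of these genes all 6 pineal libraries lay above all 6 retina libraries.

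Aanat was higher in the pineal gland as well (5.05, adjusted p = 0.00204). With ZT7 and ZT19 alone its adjusted p was 0.0637, in a range from 0.000582. Dio2 did not differ past the threshold (0.08, adjusted p = 0.922), and its value turned to -0.60 without pineal ZT19 (adjusted p = 0.00947, in a range up to 0.988).

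Photoreceptor genes differed in both directions. The rod transducin gene Gnat1 stood at 2954 ± 543 against 1.32 ± 0.277 FPKM in the pineal gland (SD, n = 6 each; log2 difference -10.30, SE 0.12, adjusted p = 1.21e-17). The calcium sensor gene Rcvrn (-8.32), the rod phosphodiesterase genes Pde6b (-8.11) and Pde6a (-7.62), the axoneme gene Rp1 (-7.80) and the rod factor gene Nrl (-7.05) were lower in the pineal gland too. Gngt1, another rod transducin gene, was lower there as well (-0.81, adjusted p = 0.0156), at 669.5 ± 227 against 1177 ± 386 FPKM. Higher in the pineal gland were the cone transducin gene Gngt2 at 908 ± 107 against 29.2 ± 3.59 FPKM (4.91) and the cone phosphodiesterase gene Pde6c (4.32). Gnb3 stood at 809.8 ± 75.2 against 56.6 ± 3.24 (3.81) and Gnat2 at 474 ± 71.6 against 35.4 ± 4.14 (3.70), and Slc24a2 (1.32) and Opn1sw (1.03) were higher too. Other cone genes, Pde6h (-3.68), Opn1mw (-3.96) and Arr3 (-1.32), were higher in the retina. Rod and cone genes were not tested as groups.

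Of 28 phototransduction genes 6 were higher in the pineal gland and 21 lower (6 and 21 adjusted over the list alone), and of 17 genes of photoreceptor structure 2 and 12 (2 and 12 adjusted over the list alone). Camera gave an adjusted p = 0.000398 for each, and an adjusted p = 0.305 with an estimated correlation for each. Crx did not differ past the threshold (214 ± 49.1 against 238 ± 26.1 FPKM, -0.17, adjusted p = 0.277). After quantile normalization it did (-0.61, adjusted p = 0.000606, in a range up to 0.547). Sag was lower in the pineal gland (-3.70, adjusted p = 1.13e-06).

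**Figure D4:**
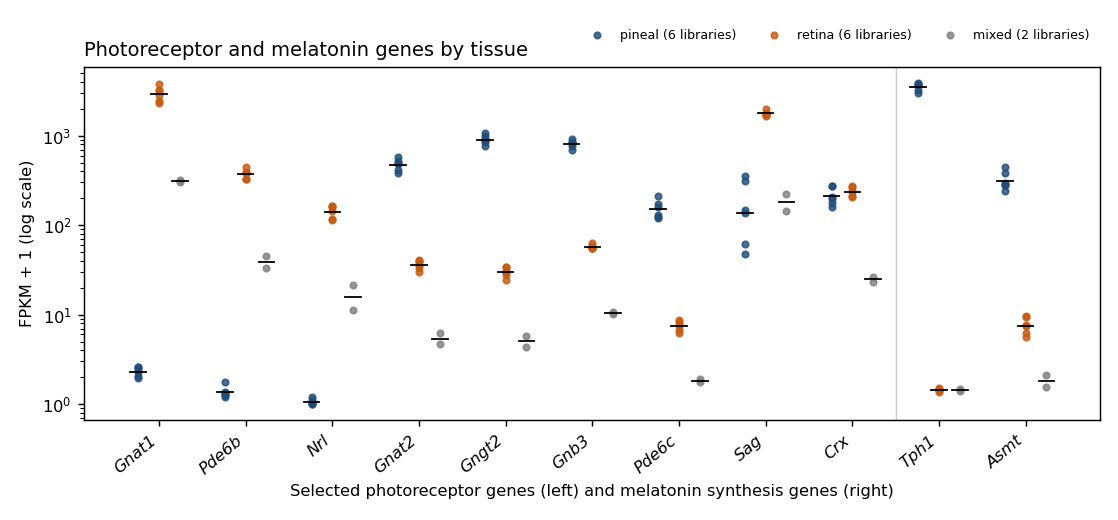
FPKM + 1 on a log axis for selected photoreceptor and melatonin synthesis genes in the pineal gland (6 libraries), retina (6) and mixed tissue (2); points are libraries and bars are means of log2 values. Gnat1 averaged 2954 FPKM in the retina and 1.32 in the pineal gland, and Gnat2 35.4 and 474.

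Cholesterol synthesis had 1 of 19 members higher in the pineal gland than in the retina and 16 lower, with a median log2 difference of -1.09 (camera adjusted p = 0.000313, and adjusted p = 0.222 with an estimated correlation). Glycolysis had 3 of 19 higher and 13 lower (adjusted p = 0.00692, and adjusted p = 0.33 with an estimated correlation), and dopamine and melatonin receptors 0 of 7 and 4 (adjusted p = 0.00542, and adjusted p = 0.0878 with an estimated correlation). Lower in the pineal gland were also amacrine and horizontal cell (0 higher and 11 lower of 12), ganglion cell (2 and 7 of 9) and pigment epithelium markers (1 and 6 of 7). Lens (0 and 8 of 8) and brain neuron markers (2 and 9 of 12) were lower too. The camera adjusted p of these 5 lists lay between 2.96e-06 and 0.0133, and adjusted p between 0.0878 and 0.33 with an estimated correlation. Blood (7 and 0 of 7, with Hbb at 906 against 63.4 FPKM), microglia (12 and 0 of 12) and meningeal markers (10 and 1 of 11) were higher in the pineal gland. Their adjusted p was 0.00036, 0.000313 and 0.000183, and adjusted p = 0.305, 0.305 and 0.3 with an estimated correlation.

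The pathway lists that did not pass were heat shock genes (12 higher and 4 lower of 18), adrenergic and cAMP signalling (10 and 4 of 20), the clock (2 and 9 of 17) and the transcription factors (6 and 6 of 15). Thyroid hormone handling (2 and 6 of 9), immediate early genes (1 and 4 of 14) and ID and BMP targets (3 and 1 of 9) did not pass either. Neither did markers of bipolar cells (3 and 5 of 10), glia (3 and 4 of 9), endothelium (5 and 1 of 7), choroid plexus (4 and 1 of 10) and oligodendrocytes (5 and 1 of 10). The same held for liver (2 and 0 of 10), muscle (1 and 5 of 12), kidney, lung and intestine (2 and 0 of 12) and pituitary and adrenal (0 and 2 of 12). Adjusted over the list alone, the counts of all lists were the same except for heat shock genes (14 and 4), the transcription factors (7 and 6) and bipolar cells (3 and 6). In all, 4296 of 11656 genes were higher in the pineal gland and 3734 lower, with 1982 and 2322 when ZT7 and ZT19 alone were used.

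Against mixed tissue, Tph1 was the most enriched gene in the pineal gland (log2 difference 11.26, SE 0.10, adjusted p = 1.73e-19). Gngt2 (7.49), Asmt (7.42), the factor genes Lhx4 (7.03) and Bsx (5.74), Chrnb4 (6.64), Gnat2 (6.45), Pde6c (6.36), Gnb3 (6.28) and Col8a1 (5.69) followed. The largest differences on the other side were those of genes of other organs. The growth hormone gene Gh1 stood at 3970 ± 1296 FPKM in mixed tissue (SD, n = 2) and was listed at 0 in each pineal library. Alb, Prl, Scgb1a1, Ahsg, Acta1 (-10.50), Ckm (-9.50), Mylpf (-9.26) and the myelin gene Mbp (-8.96) were lower as well. Crx (3.09, adjusted p = 1.04e-09) and Aanat (5.69, adjusted p = 0.0102) were higher in the pineal gland. The Aanat call was lost without either mixed library (ZT7 and ZT19, adjusted p = 0.065 and 0.0517, in a range from 0.00357). The median of all tested genes lay at -0.25. As deposited 2306 genes were higher and 5243 lower, against 5186 and 3572 after quantile normalization and 2537 and 5293 after median ratio scaling. Without the mixed ZT7 library 3346 were lower.

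Melatonin synthesis had 8 of 11 members higher than in mixed tissue and 3 lower (camera adjusted p = 0.000269, and adjusted p = 0.0265 with an estimated correlation). Markers of liver (0 higher and 9 lower of 10), muscle (0 and 12 of 12), kidney, lung and intestine (0 and 12 of 12) and pituitary and adrenal (0 and 12 of 12) were lower. Their calls held, with adjusted p between 0.0265 and 0.0319 with an estimated correlation. Calls of 8 further lists were lost with an estimated correlation. These were the transcription factors (10 and 4 of 15, adjusted p = 0.000903, then 0.0543), photoreceptor structure (10 and 3 of 17, adjusted p = 0.000886, then 0.319) and phototransduction (14 and 9 of 28, adjusted p = 0.0082, then 0.418). On the lower side were cholesterol synthesis (1 and 18 of 19, adjusted p = 0.00011, then 0.115), oligodendrocytes (0 and 10 of 10, adjusted p = 9.76e-06, then 0.0921) and amacrine cells (0 and 11 of 12, adjusted p = 0.00316, then 0.231). Microglia (0 and 11 of 12, adjusted p = 0.041, then 0.57) and endothelium (0 and 7 of 7, adjusted p = 0.0442, then 0.47) followed. Each of these counts was the same when adjusted over the list alone.

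The retina, itself part of the mixed pool, exceeded it most in lens genes. Crygc stood at 153.1 ± 202 against 0.825 ± 0.737 FPKM (log2 difference 5.50, adjusted p = 9.8e-05), and Crygd, Crygs, Crygb, Cryba2, Grifin and Mip differed by 3.83 to 5.50. The mean of Crygc rests on the retina ZT19 and ZT1 libraries (541 and 208 FPKM, against 21.3 to 81.3 in the others), and its log2 difference was 4.94 without ZT19 and 5.22 without ZT1. The photoreceptor genes Gngt1 (3.49), Aipl1 (3.44) and Prph2 (3.39) followed. Gh1, Alb, Prl, Scgb1a1, Ckm, Mylpf, Mbp (-8.89), Ahsg, Sftpc and Acta1 (-8.80) were the largest differences on the lower side. In all, 2148 genes were higher and 5434 lower, around a median of -0.30. Quantile normalization gave 5134 and 3592 and median ratio scaling 2953 and 5031, and 3360 were lower without the mixed ZT7 library.

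Above both retina and mixed tissue stood 1254 genes in the pineal gland, led by Tph1, Bsx, Chrnb4, Col8a1, Asmt, Esm1, Lhx4, Prss53, Gch1 and Gngt2. Prss53 stood at 105.7 ± 25.5 FPKM (SD, n = 6), against 1.61 ± 0.475 in retina and 2.03 ± 0.571 in mixed tissue. The count was 2294 after quantile normalization and 392 with ZT7 and ZT19 alone.

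In the mixed pools, with 1 library per time and no replicate check, Per2 stood at 3.09 FPKM at ZT7 and 8.2 at ZT19, and Cry1 at 4.73 and 9.03. Nr1d1 stood at 35 and 13 and Dbp at 25.6 and 13.8. Arntl (8.53 and 8.16) and Per1 (9.52 and 9.41) were closer.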

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

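The Ttr scaling test and the lens and phototransduction tests were chosen after the result was seen. The choroid plexus test and the other splits of the libraries were set before.

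Ttr, which codes for a thyroid hormone carrier, stood at 3566 FPKM in the pineal ZT15 library and between 663.5 and 1152 FPKM in the other 5 pineal libraries (log2 ratio 1.83). Scaling of that library is argued against, since the median log2 ratio of the 3914 genes of at least 10 FPKM was 0.059. Choroid plexus tissue in the ZT15 pool is a candidate explanation: 7 further choroid plexus genes had a median log2 ratio of 1.899, and 6 of 7 were highest at ZT15 (Sostdc1 18.9 against at most 4.57 FPKM, Clic6 16.2 against 6.05, Kl 14.1 against 5.12, Kcnj13 13.8 against 4.99; Steap1 was the exception, 1.19 against 1.21). The other 5 pineal libraries also held all 7 genes, at means of 0.525 to 4.3 FPKM, so the list is not free of pineal expression. With 1 library at ZT15, an effect of the time of day itself was not tested and stays open.

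Lens genes were uneven over the retina libraries, with Crygc at 208, 21.3, 31.6, 35, 541 and 81.3 FPKM from ZT1 to ZT23. Lens tissue in some retina pools is a candidate explanation: the 8 lens genes moved together (mean pairwise correlation 0.964, lowest 0.888), 8 of 8 were highest at ZT19, and 8 of 8 were lower at ZT23 than at ZT19 and ZT1. All 8 were above 1 FPKM in each retina library, so the list does not tell lens tissue from lens gene expression within the retina. A 24-h rhythm of lens genes cannot be told apart from it with 1 library per time: 1 of 8 passed the rhythm test (Mip), and 8 of 8 had an unadjusted p under 0.05.

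In the pineal gland 11 phototransduction genes were rhythmic, with Sag from 46.9 FPKM at ZT1 to 350.4 at ZT15. Retinal RNA in the pineal pools is argued against, since that rise of Sag, at the ratios seen in the retina, would bring 503 FPKM of Gnat1, 76.8 of Pde6a and 64.2 of Pde6b, against 1.49, 1.11 and 0.76 FPKM at ZT15 (at most 1.449% of the expected level) and at most 1.65 FPKM of each in the 6 pineal libraries. Scaling of the libraries is argued against as well: 10 of the 11 genes passed after quantile normalization and 11 after median ratio scaling. A rhythm of these genes within the pineal gland is therefore kept as a hypothesis, found and tested on the same libraries.

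Of 30 groups of 6 libraries tested for a single distant value 6 had one, where chance gives about 1 in 20. In the pineal gland ZT19 had the lowest summed FPKM (163087 against 174889.3 to 180522.1, gap 0.677 of the range). ZT23 had the highest mean log2 of the lens markers (1.50 against 0.33 to 0.51, gap 0.843), with Crygc at 2.53 FPKM. ZT19 had the lowest blood markers (5.36 against 5.97 to 6.34, gap 0.628). In the retina ZT7 had the highest summed FPKM (179277.5 against 152281 to 161184.1, gap 0.67). ZT19 had the lowest pigment epithelium (2.59 against 3.01 to 3.19, gap 0.7) and choroid plexus markers (2.36 against 2.70 to 2.87, gap 0.666).

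The 24-h rhythm differed between the tissues for 516 genes by a test of the difference. With values centred per tissue the count was 443. Of 32 swaps of tissues within times, the real arrangement included, 1 gave as many (highest other 314). As 1 of 32 is the lowest rank possible, chance is unlikely for the centred count but not excluded. Without single libraries the count ran from 178 (retina ZT23) to 828 (pineal ZT7), with 188, 193, 221, 237, 251, 286, 314 and 797 without retina ZT13, retina ZT7, retina ZT1, pineal ZT23, retina ZT15, retina ZT19, pineal ZT13 and pineal ZT19, and it was 25 without retina ZT1 and ZT19. The larger pineal rhythms were those of Slc15a1 (fitted peak to trough 9.07 in the pineal gland and 0.05 in the retina, adjusted p of the difference 0.00625), Aanat (8.79 and 2.33, 0.0141), Atp7b (7.74 and 2.19, 0.0295), Hhip (5.57 and 0.17, 0.000217) and Fcer1a (5.57 and 0.41, 0.0338). Further ones were Drd4 (5.39 and 2.05, 0.021), Crem (5.18 and 0.29, 0.0348), Ribc2 (4.75 and 0.23, 0.00914), Sag (2.80 and 0.21, 0.000325), Dbp (2.53 and 0.52, 0.000554), Nr1d1 (2.49 and 0.48, 0.000239) and Arntl (2.22 and 0.33, 0.00502). The larger retinal rhythms were those of Ctnnal1 (0.46 in the pineal gland and 2.20 in the retina, 0.00436), Asns (0.67 and 1.87, 0.0462), Ypel4 (0.32 and 1.87, 0.0107) and Mast2 (0.38 and 1.76, 0.0103).

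The late dark effect differed for 74 genes, and after centring 4 of 32 arrangements gave at least the real 69 (highest other 79), so chance is not excluded for the count. It ran from 7 (without retina ZT19) to 384 (without pineal ZT1), with 10, 22, 28, 30, 36 and 186 without retina ZT23, retina ZT7, pineal ZT19, retina ZT13, pineal ZT7 and pineal ZT23. The pineal minus retina differences were 4.22 for Irs2 (adjusted p = 0.000571), 4.17 for Sik1 (0.000571), 3.73 for Dclk3 (0.00986), 3.62 for Ptch1 (0.000475), 3.55 for Zrsr1 (0.00146), 2.60 for Dusp1 (0.0113), -2.16 for Ptpn21 (0.011), -1.82 for Sgk1 (0.0201) and -1.71 for Cfl2 (0.0131). The differences of single genes in this paragraph and the last were tested with all libraries only.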

How the results depend on the processing

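The alternatives without retina ZT1 and ZT19 together and with transcripts not summed per gene were chosen after the data were seen; the others were set before. Of 3662 values of named genes under the alternatives set before 3463 kept their side of the threshold, 161 were no longer past it and 37 were newly past it. A further 1 reversed (Dio2, pineal gland against retina, 0.08, which became -0.60 without pineal ZT19, with a range over left-out libraries up to 0.29, without pineal ZT15). A change of sign was counted only for values past the threshold in at least 1 of the fits compared. For rhythms neither sign nor peak time was compared. Grouping ZT15 with the dark libraries ended the calls of 21 of these values, and the 22 others passed in neither fit. Fitting each tissue alone ended the calls of 15, and the missing filter those of 12. Of the values in these 2 settings 64 and 164 kept their side of the threshold, whether past it or not. Depth limits weak genes most: by the rough estimate above, 1 fragment in a transcript of 1 kb was worth 0.0216 FPKM in the deepest library and 0.0527 in pineal ZT19, the shallowest. All splits of libraries were set before. Of 100 orderings of the times, the real one included, 2 gave at least the real 2160 rhythmic pineal genes (highest other 3571). For the 106 of the retina it was 1 of 100 (highest other 93). Chance is therefore unlikely but not excluded, and 1 other ordering called more pineal genes. For pineal gland against retina it was 1 of 100 splits (4296 higher and 3734 lower, highest other 4142 in all). Each other split mixed the tissues and so put their difference into the error, so this rank does not weigh chance. More splits reached the real count for late dark, where chance is not excluded either. In the pineal gland it was 4 of 60 splits (317 higher and 441 lower, highest other 2143). In the retina it was 19 of 60 (1 and 0, with 166 and 1072 at an unadjusted p under 0.05 on the deposited scale, highest other 140). The split with 2143 and the one with 140 were alike, with ZT1 as the single library, ZT7, ZT13 and ZT15 as light, and ZT19 and ZT23 as late dark. They call several times the real count, which points to a structure of the samples in which ZT1 stands apart from the light libraries and ZT15 does not.

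The values below moved by over 1.5 times, and the cause was not tested unless given. Counts are of genes in limma's tests, higher and lower where paired. With a pseudocount of 0.1 the retina had 58 rhythmic genes, 35 with peaks in the light, and 0 genes higher in late dark (151 unadjusted). Without a filter more genes were tested, with 64 rhythmic in the retina (41 in the light), 324 differences of rhythm, 197 and 280 for late dark in the pineal gland, 4 and 1 in the retina and 12 differences of late dark effects. With at least 5 FPKM in 2 libraries fewer were tested, with 0 higher in late dark in the retina (127 unadjusted) and 3363 lower in the pineal gland than in mixed tissue. Quantile normalization gave 173 rhythmic genes in the retina (99 in the dark), 252 lower in late dark in the pineal gland, 5186 higher there than in mixed tissue, 5134 and 3592 for retina against mixed tissue, and 2294 above both. Median ratio scaling gave 484 and 273 for late dark in the pineal gland and retina peaks of 39 in the light and 85 in the dark. Each tissue alone has 3 residual degrees of freedom and its own error: 535 rhythmic pineal genes (311 light, 224 dark), 781 in the retina (654 light, 127 dark), and 69 and 52 for late dark in the pineal gland. The order of the tissues by rhythmic genes was thereby reversed.

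With all dark against all light libraries 0 and 0 genes passed in the pineal gland (403 and 802 unadjusted), 0 were higher in the retina (53 unadjusted) and 0 effects differed (481 unadjusted). With a mean of its own for ZT1, late dark gave 532 and 1046 in the pineal gland, 50 and 54 in the retina and 340 differences. With ZT7 and ZT19 alone, and so fewer libraries, 1982 and 2322 differed between pineal gland and retina, 1306 and 1323 were higher in pineal gland and retina than in mixed tissue, and 392 stood above both. Without retina ZT1 and ZT19 the pineal gland had 1053 rhythmic genes (672 light, 381 dark), the retina 4 (0 light, with 938 unadjusted, and 4 dark), and 25 rhythms differed. Late dark then gave 158 and 178 in the pineal gland, 0 higher in the retina (134 unadjusted) and 8 differences. With an estimated correlation the lists past the threshold went from 5 to 0 (pineal late dark), 4 to 0 (retina late dark), 14 to 1 (pineal gland against retina) and 13 to 5 (against mixed tissue), in camera, and 36 of 112 list tests in all became 6. Summing transcripts, the time of day as a block and the mean-variance trend moved no count by over 1.5 times.

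Leaving out each library in turn gave these ranges, each with the libraries left out at its ends. Where an arm kept 1 library, that library was assumed to vary like the others. Pineal rhythmic genes were 889 to 2620 (pineal ZT23, ZT7), 572 to 1926 in the light (ZT23, ZT7) and 317 to 793 in the dark (ZT23, ZT19). Retina rhythmic genes were 12 to 415 (retina ZT1, pineal ZT19), 4 to 329 in the light (retina ZT23, pineal ZT19) and 7 to 86 in the dark (retina ZT1, pineal ZT19). Differences of rhythm were 178 to 828 (retina ZT23, pineal ZT7). Late dark gave 90 to 538 higher and 73 to 1062 lower in the pineal gland (pineal ZT19, ZT1 for both), 0 to 39 higher (retina ZT19, with 65 unadjusted, and ZT1) and 0 to 35 lower in the retina (ZT1 for 35), and 7 to 384 differences (retina ZT19, pineal ZT1). Pineal gland against retina gave 4077 to 4494 higher and 3546 to 3754 lower. Against mixed tissue the pineal gland had 1592 to 2475 higher (mixed ZT19, pineal ZT19) and 3346 to 5271 lower (mixed ZT7, pineal ZT15), the retina 1468 to 2270 higher (mixed ZT19, pineal ZT19) and 3360 to 5601 lower (mixed ZT7, retina ZT7), and 842 to 1369 stood above both (mixed ZT19, pineal ZT19).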

Other observations

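Pineal night genes differed in how much of their rise was left 1 h after lights on. The genes taken were the 224 that passed the test (adjusted p under 0.05) and were at least 2-fold higher at ZT19 and ZT23 than at ZT7 and ZT13 in a fit that gave ZT1 its own mean, a selection made after the values were seen. Of the log2 rise of each gene a median of 49.2% was left at ZT1 (quartiles 22.4% and 73.9%), with at least 50% left in 109 genes and under 25% in 62. The enzyme gene Aanat kept 86% (396 FPKM at ZT1, against 6.7 by day and 754 in late dark), the dopamine receptor gene Drd4 92.8%, Hhip 93.9%, Atp7b 82.8%, the chaperone gene Hspa5 78.9% and Slc15a1 77.5%. Crem kept 47.4%. The phosphatase gene Dusp1 kept 11.3%, the hedgehog receptor gene Ptch1 16.2%, Nr4a1 3.7%, the kinase gene Sik1 1.4% (1.9 FPKM at ZT1, against 1.79 by day and 56.2 in late dark) and the homeobox gene Bsx 0.1%. Irs2 and Pde4b stood below their daytime level at ZT1 (-8% and -20.8%). Each time had 1 library, so these shares have no error of their own. A share of a log2 rise also depends on the size of the rise: Slc15a1 kept 77.5% at 69.5 FPKM, against 213 in late dark. The late dark level is the mean of ZT19 and ZT23, so a fall that began before lights on is not told apart from a later one.

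Of the 35 genes rhythmic in both tissues 6 had peaks more than 6 h apart, named here after their values were seen. Pspc1, a paraspeckle gene, peaked at ZT21.8 in the pineal gland and at ZT8.52 in the retina (10.8 h apart, 11.9 FPKM at pineal ZT23 and 13.5 at retina ZT7, adjusted p of the rhythm difference 0.00339). Fabp12, a fatty acid binding protein gene, peaked at ZT8.91 in the pineal gland (48.9 FPKM at ZT7 and 23.7 at ZT19) and at ZT22.3 in the retina (15.4 and 34.5), 10.6 h apart (0.000346). Dcakd (7.5 h, 0.0112), Cds1 (7.25 h, 0.0164), the taurine transporter gene Slc6a6 (7.02 h, 0.00238) and Dctpp1 (6.2 h, 0.0152) followed. By contrast the cilium gene Bbs4 peaked at ZT23.8 and ZT23.5 and Ndrg3 at ZT0.46 in both. These genes were not followed under the alternatives.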
